A study of Homo sapiens with 30 samples.

How the data were processed

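The series held 30 human RNA sequencing libraries that the labels class as single-cell transcriptomes. 26 came from sections of breast cancer tissue and 4 from MCF-7, an established oestrogen receptor positive breast cancer cell line. Per the labels' protocols, mRNA was isolated with NVIGEN nanoparticles and libraries were made with a single-cell protocol of the same supplier. The titles name nanopipette or control material, an NV label (NV1, NV13 or NV17) or direct RT, and for some libraries 3day or a code, called set A and set B here. The labels do not explain these terms, and they give 1 extraction protocol for every library, including those titled direct RT.

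The deposited files hold raw read counts per gene, as whole numbers, with 4 summary lines for reads that were unmapped, aligned to several places, outside any exon or ambiguous between genes. Trimmomatic 0.36, STAR and HTSeq, and the genome builds GRCh38 and hg38, are named per the submitters' processing notes. Those notes give no order of steps, and the versions of STAR and HTSeq, the annotation release and any use of molecular identifiers are not given in the sources used here. The layout of the deposited counts, 3 columns per gene of which the first is unstranded, is that of STAR's own gene counting. The unstranded column was used, because it held 9476 gene reads against 6417 and 4038 in the strand columns. Reads from a gene and an overlapping or antisense gene can therefore be mixed.

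Each file had 60070 gene rows, of which 56494 were found in GENCODE 29 and 56067 had a symbol. Positions are from GENCODE 29 on GRCh38, 1-based. None of the 37 mitochondrial-chromosome genes of GENCODE 29 was among the rows used, so the mitochondrial measures that had been planned were not analysed here. Before any gene-level work, 1142 rows were set aside for privacy (sex-linked marker genes, HLA, antigen receptor segments and genes commonly deleted in people). They stayed in the gene read totals behind shares and pooled folds, but not in the library sizes of the gene-level fits. Rankings, recurrence, sharing between libraries, correlations and lists used only genes with a symbol and a GENCODE 29 position. With the privacy rows, this left out 184 of the 1579 rows with a read, holding 866 reads. Genes detected per library counted all rows. All value columns of the files were of a known kind.

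Libraries were grouped by title into 11 groups, 7 of them with 2 or more libraries. Replicate numbers only name a library. The labels name no donor or culture and do not say whether libraries came from separate cells or sections, so p-values measure only the spread between these libraries, which may be technical. For each library the unmapped, multimapping and assigned shares of all reads, the share of uniquely aligned reads that fell on exons, total reads and genes detected were compared between groups. The test was a two-sided exact permutation test of the difference of means, permuted within set or NV label where these were balanced, with Benjamini-Hochberg adjustment over 30 tests. Intervals of single-library shares are 95% exact binomial intervals. The floor for a count of 0 was 3 counts. The libraries have no known molecular identifiers, so intervals and floors cover counting error only.

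Gene counts were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM) in R 4.3.3 on the 26 libraries of the 7 groups in 1 group-means model, at a Benjamini-Hochberg adjusted p under 0.05. The SE printed with a fitted log2 fold change was worked back from the test, as its absolute value divided by the square root of F. It is only a rough guide, above all where a group had 0 reads of the gene. The intended low-count filter, filterByExpr by group, left 1 gene, C17orf78, and TMM could not be computed on it. The fit without a filter, which had been intended as a second setting, is therefore the fit reported, on 1319 genes. Its TMM factors ran from 0.142 to 33.8, far outside the range over which scaling is trustworthy. The fit was repeated with TMM with singleton pairing, library size only, DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom with quality weights (limma 3.58.1), only the groups compared, the larger strand column, and leaving out each library in turn. The test was tried on simulated counts for NV1 against NV17 with 200 changed genes. The counts were drawn from 1 pooled composition shared by all libraries, with a negative binomial size of 5. That size was set and not estimated from these libraries. Most real genes had reads in 1 library only, so the simulated spread may be too small and the recovered shares too high. At the real depth the test recovered 0% of 4-fold and 51% of 16-fold changes. The latter were 102 genes, beside 14 false calls among 1043 genes, a larger part of the calls than the 0.05 aimed at. At 1000 times the depth, on 1319 genes, the test recovered 98% and 100%, with 13 and 22 false calls.

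23 gene lists were fixed in advance: ribosomal proteins, mitochondrial mRNA and rRNA, markers of luminal, basal, fibroblast, endothelial, macrophage, lymphocyte, adipocyte, erythrocyte and keratinocyte cells, immediate early and heat shock genes, oestrogen response, genes amplified in MCF-7, proliferation, replication histones, nuclear long noncoding RNA, small RNA without poly(A), housekeeping, glycolysis and hypoxia, and nuclear-encoded oxidative phosphorylation. Lists with 5 or more members with a read were tested with camera (preset correlation 0.01, and an estimated one) and fry. Libraries in each group with 1 library were described without a test, with log2 ratios after adding 0.5 to each count. Named genes were set by rule: every gene past the test, the 10 genes with the highest mean CPM (counts scaled to library size) over the libraries compared, and up to 4 members of each list, and for the single control libraries genes with 20 or more counts summed. These choices, the groups, the tests and the repeated fits, apart from those named below, were fixed before the data were examined.

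Chosen after the data were seen were: total reads and exon share as measures, rarefaction to 30 gene reads, leaving out libraries under 10000 reads or under 30 gene reads, list tests without a filter, list shares per library, lists matched on exon length (10000 random lists, within 100 ranks of length), pooled folds, tables of the genes with most reads and in most libraries, and all tests of explanations. Testing genes detected without rarefaction was also chosen then, because 0 libraries reached the planned depth of 10000 gene reads. That number rises with depth. Pooled folds divide a gene's share of the gene reads of one group of libraries by that of the other, with 95% exact intervals. A gene with 0 reads in one group was set against 3 reads over that group. Folds worded as "at least" used this floor and took the other group's count as free of error. They are therefore not limits of 95% intervals, and the smallest of them need not mark a difference.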

Results

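RNA libraries were sequenced from small samples of breast cancer tissue and of MCF-7 cells to compare ways of taking and isolating RNA from single cells in place. Tissue sampled by nanopipette gave 8 libraries labelled NV1 and 8 labelled NV17, 4 of each in set A and 4 in set B, and 6 libraries labelled direct RT. MCF-7 sampled by nanopipette gave 2 NV1 libraries of set A. Control material gave 2 tissue libraries by direct RT and 4 single NV13 libraries, from MCF-7 and tissue, each with and without a 3day label. The 30 libraries held 2400116 reads, from 352 to 662061 per library, of which 94.4% were unmapped, 4.68% aligned uniquely outside exons, 0.534% aligned to several places and 0.395% (9476 reads) were assigned to 1 gene. Gene reads per library had a median of 95, and 15 libraries had fewer than 100. Replicate 1 of tissue NV1 set A held 62.8% of all gene reads, and the next deepest library held 435.

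**Figure D1:**
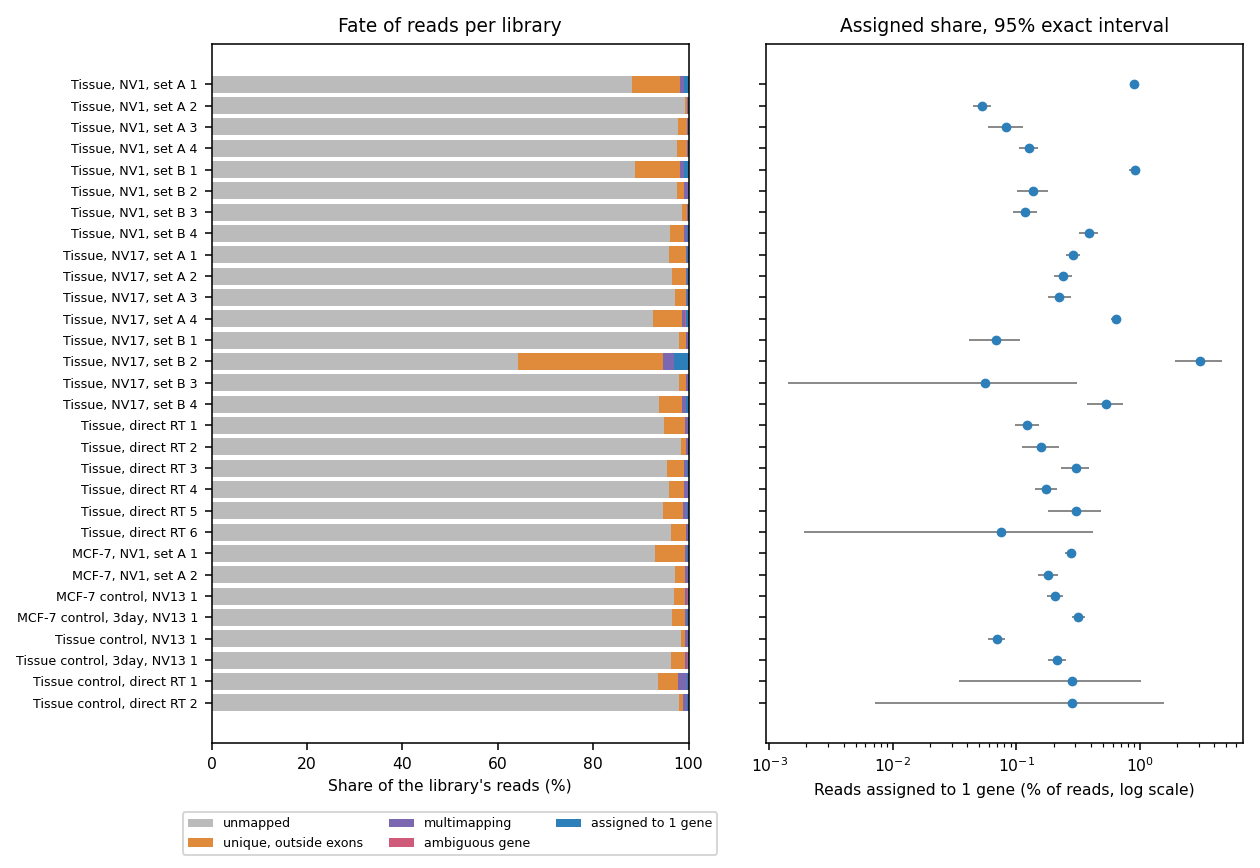
Fate of the reads of each of the 30 libraries, as stacked shares of the library's reads in percent (left), and the share assigned to 1 gene on a log axis with its 95% exact binomial interval (right). Replicate 2 of tissue NV17 set B had 64.3% unmapped reads and 3.04% assigned reads.

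The genes with the most reads were SLC25A3, the mitochondrial phosphate carrier (chromosome 12, 98593591 to 98606379), with 153 reads in 6 libraries, and SCARB1, a receptor for high-density lipoprotein, with 129 reads in 2. They were followed by RSAD1 (114 reads), PEBP1, an inhibitor of Raf kinase signalling (110 reads), TFF3, a secreted trefoil factor of luminal breast cells (104 reads), and PLIN4, a lipid-droplet protein (103 reads). Nearly all of these reads were in the deepest library, which held 129, 123, 113, 109, 102 and 102 of them in that order. In the other 29 libraries together the leading genes were NAV2 (83 reads), RGPD8 (64), EFR3B (61), C17orf78 (57) and PFKFB3, a regulator of glycolysis (46). NAV2, EFR3B and PFKFB3 each had all of those reads in 1 library. RGPD8 belongs to a family of near-identical genes, so its reads are uncertain.

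Few genes recurred. Of 1395 genes with a read, 1183 (84.8%) had reads in 1 library, 212 in 2 or more, 8 in 5 or more and none in more than 10, and 914 genes had 1 read in all. The widest spread was that of BRCA1 and BRCA2, DNA repair genes, and of the pseudogene KARS1P3, each with a read in 10 libraries. MARCHF6, a ubiquitin ligase, followed with 7, then HSPA8, the constitutive heat shock cognate protein, and SLC25A3 with 6 each, and UQCRH, a respiratory chain subunit, and the mitochondrial pseudogene MTCO1P12 with 5 each. A mitochondrial origin of the MTCO1P12 reads could not be checked, since mitochondrial-chromosome genes were not among the rows used. Across the 1395 genes, the median Spearman correlation between libraries was -0.00315 over 41 pairs within groups and -0.00803 over 394 pairs between groups. Genes are not independent replicates, so these correlations only describe the libraries.

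**Figure D2:**
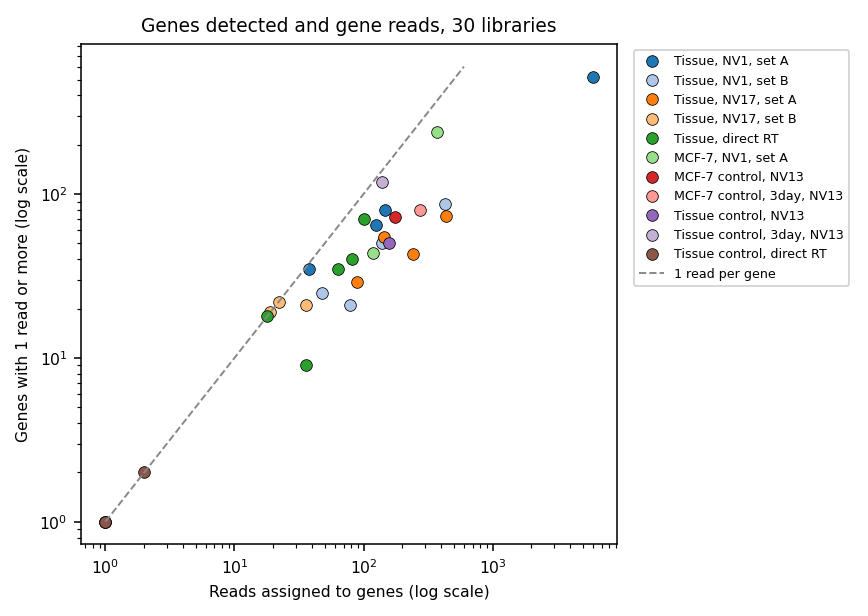
Genes with 1 read or more against reads assigned to genes, both on log axes, 1 point per library, coloured by group, with a dashed line at 1 read per gene. The deepest library had 517 genes, and 3 libraries had 1 gene each.

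Ribosomal protein genes were the best covered of the fixed lists. 27 of the 78 had a read, with 408 reads in 16 libraries, and 260 of these reads were in the deepest library. The other 29 libraries held 148 reads of 22 members in 15 libraries. Random lists matched on exon length had a mean of 3.85 members with a read and never more than 14 (permutation p = 0.0001, the smallest that 10000 lists can give). Without the deepest library the values were 22 against a mean of 2.70 (permutation p = 0.0001).

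The luminal list had 8 of 31 members with a read, against a mean of 1.73 in matched lists (permutation p = 0.0001). They were TFF3, TFF1, the transcription factor GATA3, the oestrogen and androgen receptors ESR1 and AR, the keratin KRT19, the adhesion protein EPCAM and the receptor ERBB2, with 163 reads of which 144 were in the deepest library. The other 29 libraries also held 8 members, with 19 reads, against a mean of 1.28 (permutation p = 0.0001). Housekeeping genes had 6 of 20 members with a read (ACTB, B2M, EEF1A1, FTL, UBC and POLR2A; 58 reads; permutation p = 0.0002) and heat shock genes 4 of 13 (HSPA8, HSP90AA1, HSP90AB1 and HSPB1; 46 reads; permutation p = 0.0025). Without the deepest library, which held 46 of the 58 housekeeping reads, 2 housekeeping members remained (12 reads, permutation p = 0.189) and 3 heat shock members (34 reads, permutation p = 0.0120).

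None of the other protein-coding lists, which alone were set against length-matched lists, had more members with a read at a permutation p under 0.05, the closest being oxidative phosphorylation with UQCRH, ATP5F1A and ATP5PO (18 reads, permutation p = 0.0608) and fibroblast genes with SPARC, PDGFRA, FBLN1 and VCAN (9 reads, permutation p = 0.0818). The oestrogen response list had TFF1, CA12 and SLC39A6 with 65 reads (permutation p = 0.130), the glycolysis list PFKFB3 and HK2 with 48 (permutation p = 0.366), and the endothelial list TEK and ERG with 2 (permutation p = 0.261). 1 member each was seen of the adipocyte list (PLIN4, 103 reads), the list amplified in MCF-7 (BCAS1, 32 reads), the long noncoding list (MALAT1, 20 reads), the keratinocyte list (S100A7, 9 reads), the proliferation list (PLK1, 1 read) and the histone list (H1-2, 1 read). No read fell on the basal, macrophage, lymphocyte, erythrocyte or immediate early lists or on small RNA without poly(A), which allows a share of up to 0.0317% of the 9476 gene reads for each, or 0.0852% of the 3523 outside the deepest library.

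**Figure D3:**
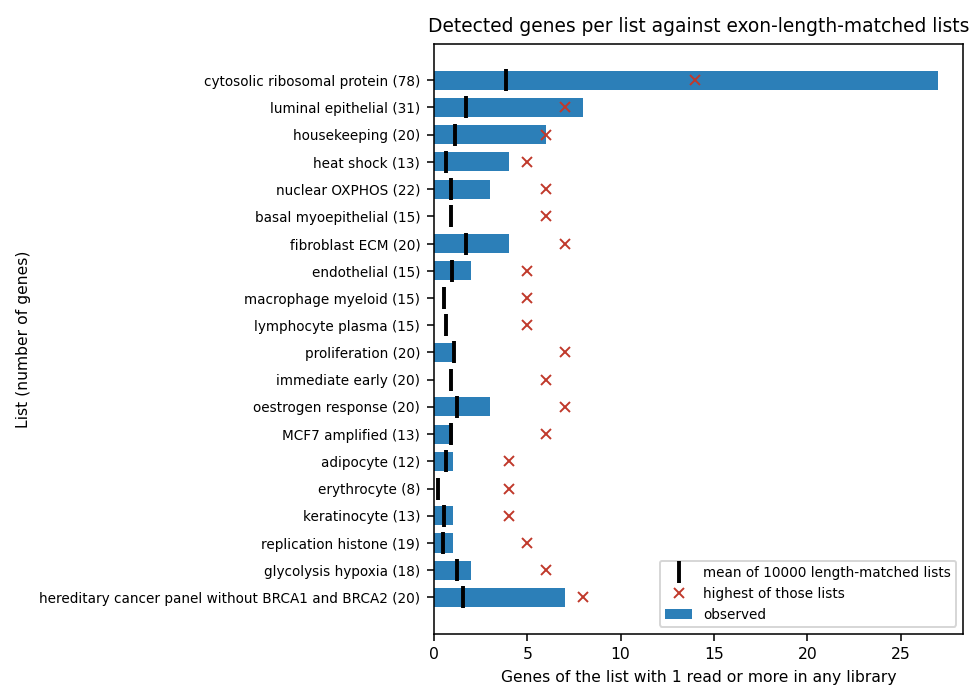
Number of genes of each list with 1 read or more in any library (bars), with the mean (black line) and the highest value (red cross) of 10000 random lists matched on exon length. The ribosomal protein bar reached 27 where the highest random list reached 14.

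**Figure D4:**
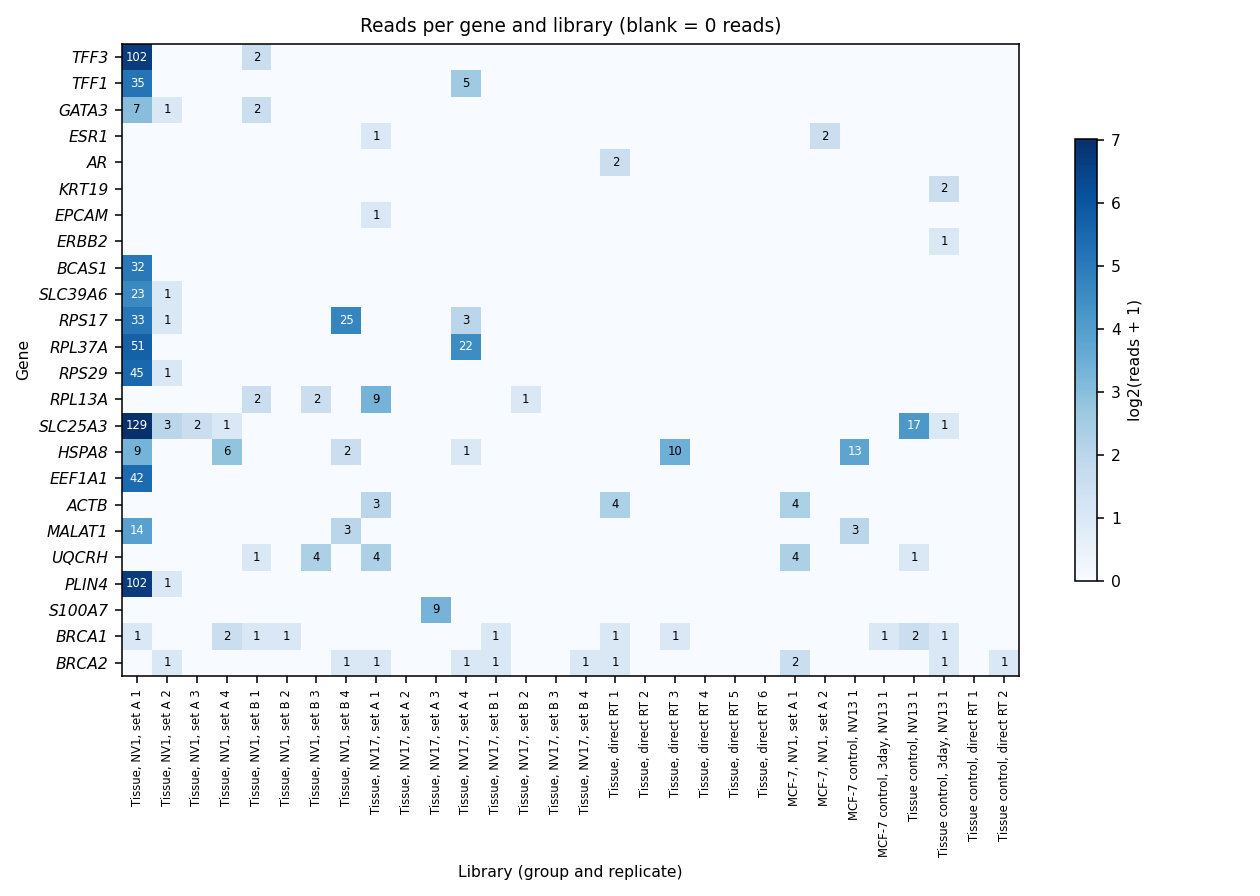
Reads of 24 genes in each library, with the number of reads printed in each cell and colour on a log2(reads + 1) scale. TFF3, PLIN4 and SLC25A3 had over 100 reads in replicate 1 of tissue NV1 set A, while BRCA1 and BRCA2 never had more than 2.

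The first comparison asked whether NV1 and NV17 gave different RNA from nanopipette samples of tissue. TFF3 had 104 of 6956 gene reads in the NV1 libraries and 0 of 985 in NV17, at least 4.91-fold higher in NV1, and PLIN4 had 103 against 0, at least 4.86-fold higher. Both rested on the deepest library, since the other 7 NV1 libraries held 2 reads of TFF3 and 1 of PLIN4 in 1003. GATA3 had 10 reads in 3 NV1 libraries and 0 in NV17, and MALAT1, a nuclear long noncoding RNA, had 17 reads in 2 NV1 libraries and 0 in NV17, which sets no bound above 1 for either, and 7 and 14 of these reads were in the deepest library. Higher in NV17, EFR3B, which anchors a lipid kinase at the plasma membrane, had 61 reads in 1 NV17 library and 0 in NV1, at least 144-fold higher, and the adaptor protein NCK1 had 32 against 0, at least 75.3-fold higher, also in 1 library. The keratinocyte gene S100A7 had 9 reads in 1 NV17 library and 0 in NV1, at least 21.2-fold higher. The last 3 bounds also rest on the deepest library, and without it they were 20.7-fold, 10.9-fold and 3.05-fold.

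Ribosomal protein genes took 8.30% ± 10.1 (SD, n = 8) of gene reads per NV1 library and 2.39% ± 3.89 (n = 8) per NV17 library (exact permutation p = 0.156, adjusted p = 0.543). 7 of 8 NV1 libraries and 3 of 8 NV17 libraries had such a read. Without replicate 4 of NV17 set A the difference grew from 5.91 to 7.10 percentage points (exact permutation p = 0.0208, not adjusted), and without replicate 3 of NV1 set B it shrank to 3.33 (exact permutation p = 0.261). RPS17 had 59 reads in 3 NV1 libraries and 3 in 1 NV17 library (pooled ratio 2.78, interval 0.908 to 13.9), while RPL37A had 51 in 1 and 22 in 1 (ratio 0.328, interval 0.196 to 0.57). Without the deepest library RPS17 had 26 against 3 (ratio 8.51, interval 2.61 to 43.9) and RPL37A 0 against 22. Of those 26 reads 25 were in replicate 4 of NV1 set B, and with that library left out too the ratio turned to 0.380. All 22 reads of RPL37A were in replicate 4 of NV17 set A. Camera called the list higher in NV1 (adjusted p = 0.0356), with an adjusted p = 0.958 with an estimated correlation, and fry put the list lower in NV1 (adjusted p = 0.520). The processed pseudogenes RPL12P14 and RPL13AP5, whose reads cannot be told from those of RPL12 and RPL13A with certainty, had 40 and 31 reads in NV1 and 0 in NV17, with 39 of the 40 in 1 library.

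Among other lists, TFF1 had 35 reads in 1 NV1 library and 5 in 1 NV17 library (ratio 0.991, interval 0.387 to 3.24), and HSPA8 had 17 in 3 and 1 in 1 (ratio 2.41, interval 0.377 to 101). All 35 reads of TFF1 were in the deepest library, without which TFF1 had 0 against 5 and HSPA8 8 against 1 (ratio 7.86, interval 1.05 to 349). EEF1A1, BCAS1 and SLC39A6 had 42, 32 and 24 reads in NV1 and 0 in NV17, with 42, 32 and 23 of them in the deepest library. Luminal genes took 0.505% ± 0.858 and 0.248% ± 0.467 of gene reads per library (n = 8 each, exact permutation p = 0.571).

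No gene passed edgeR's test between NV1 and NV17. It called 0 of 1319 genes at an adjusted p under 0.05, with 2 at an unadjusted p under 0.05, and DESeq2's Wald test called 0. Fitted log2 fold changes were 3.73 (SE 3.02) for RPS17, 4.27 (SE 2.73) for TFF3 and 2.13 (SE 2.23) for HSPA8, each with edgeR's adjusted p = 1. Limma-voom with quality weights called 1310 genes, with a median log2 fold change of -1.93 over all genes against 0.54 in the edgeR fit. All 1310 were put lower in NV1, where RPS17, TFF3 and HSPA8 took the opposite sign to the edgeR fit. Across the 15 fixed lists with a tested member, edgeR called 0 genes in any of the 5 comparisons over all genes and 0 when adjusted over the list alone. Limma-voom's calls in this comparison, 1310 of 1319 genes, included TFF3 and HSPA8.

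NV1 libraries held 158962 ± 218866 reads and NV17 libraries 36178 ± 32218 (n = 8 each, exact permutation p = 0.00816, adjusted p = 0.122), with 110 ± 166 and 33 ± 23.2 genes detected (exact permutation p = 0.0437, adjusted p = 0.262). Both adjusted values fell below 0.05 without replicate 3 of NV1 set A, to 0.00612 and 0.0398. Without the deepest library the differences shrank from 122784 to 57728 reads and from 77 to 19.9 genes, and over all left-out libraries the adjusted p reached 0.612 and 0.798. The number of genes detected rises with depth, so it cannot be told from the difference in depth. Rarefied to 30 gene reads, it was 20.7 ± 5.60 in NV1 (n = 8) and 17.4 ± 1.62 in NV17 (n = 5), given without a test. NV17 libraries with fewer gene reads could not be rarefied. Within set A the total reads differed by 208659 (exact permutation p = 0.143) and within set B by 36908 (exact permutation p = 0.0286). Unmapped, multimapping and assigned shares were 95.5% ± 4.39, 0.477% ± 0.287 and 0.338% ± 0.362 in NV1 and 92.1% ± 11.4, 0.679% ± 0.635 and 0.635% ± 0.994 in NV17, with exact permutation p = 0.604, 0.506 and 0.613.

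The second comparison set the 16 NV1 and NV17 libraries against the 6 direct RT libraries of nanopipette samples. C17orf78, an uncharacterised gene (chromosome 17, 37375986 to 37392708), had 26 of 300 gene reads in direct RT, all in 1 library, and 0 of 7941 in the NV libraries, at least 229-fold higher in direct RT, or at least 57.4-fold without the deepest library. RGPD8 had 17 reads in 1 direct RT library and 36 in 2 NV libraries (pooled ratio of NV over direct RT 0.0800, interval 0.0438 to 0.152), and HSPA8 had 10 in 1 and 18 in 4 (ratio 0.0680, interval 0.0298 to 0.165). ACTB, cytoskeletal actin, had 4 reads in 1 direct RT library and 3 in 1 NV library (ratio 0.0283, interval 0.00415 to 0.167). AR had 2 reads in direct RT and 0 in NV (ratio 0, interval 0 to 0.201, or 0 to 0.804 without the deepest library), and the fibroblast gene PDGFRA had 2 and 1 (ratio 0.0189, interval 0.000320 to 0.363). Without the deepest library the ratios of RGPD8, HSPA8, ACTB and PDGFRA were 0.0621, 0.136, 0.113 and 0.0755, the last with an interval of 0.00128 to 1.45. The direct RT reads of each of these genes and of AR were in 1 library, without which direct RT had 0 reads of the gene.

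Ribosomal protein genes took 5.34% ± 7.99 (n = 16) of gene reads per NV library and 0.412% ± 1.01 (n = 6) per direct RT library, with a read in 10 of 16 and 1 of 6 libraries (permutation p = 0.109, adjusted p = 0.543). RPS17 and RPL37A had 62 reads in 4 and 73 reads in 2 NV libraries, and RPL13A had 14 reads in 4, against 0 in direct RT for all 3. With 300 gene reads in direct RT, these counts set no bound above 1 for any of the 3 genes, while without the deepest library RPS17 (29 reads) was at least 1.46-fold and RPL37A (22 reads) at least 1.11-fold higher in NV. These 2 bounds each rest on 1 further library, with 25 and 22 of the reads, and leaving it out left no bound above 1. Both also take the NV count as free of error, so 1.11-fold does not establish a difference for RPL37A. Camera called the list higher in NV (adjusted p = 4.60e-05), with an adjusted p = 0.958 with an estimated correlation, and fry put it lower (adjusted p = 0.953). Luminal genes took 0.376% ± 0.680 and 0.412% ± 1.01 of gene reads (permutation p = 0.934). TFF3, TFF1 and GATA3 had 104, 40 and 10 reads in NV and 0 in direct RT, with 2, 5 and 3 reads left without the deepest library, and then no bound above 1 for any. With it, only TFF3 had one, at least 1.31-fold higher in NV. In direct RT, SPARC, TEK, HSP90AA1, HK2 and H1-2 had 1 read each, against 0 in NV.

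EdgeR called 0 of 1319 genes here, with 13 at an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 1318, all higher in NV (median log2 fold change over all genes 2.45, against 0.32 in edgeR). With TMM with singleton pairing or library size only, edgeR called 1 gene, C17orf78, lower in NV, at an adjusted p = 0.0448 and 0.0475. The fitted log2 fold changes in the reported fit were -10.99 (SE 3.60) for C17orf78, -1.50 (SE 1.32) for RGPD8 and -1.09 (SE 1.40) for HSPA8, each with edgeR's adjusted p = 1. Without replicate 3 of direct RT, the only one with reads of the latter genes, these became 2.06 and 1.82. The assigned share was 0.486% ± 0.739 in NV and 0.189% ± 0.0942 in direct RT, and genes detected were 71.5 ± 121 and 28.8 ± 25.1 (permutation p = 0.383 and 0.385). Direct RT titles carry no set code, so method and code cannot be separated. Total reads less those of direct RT were 138155 in set A (exact permutation p = 0.0992) and -1494 in set B (exact permutation p = 0.913).

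The third comparison set the 8 tissue libraries of set A against the 8 of set B, over both NV labels. RPL13AP5 had 31 reads in 3 libraries of set B and 0 in set A, at least 96.2-fold higher in set B (41.5-fold without replicate 3 of NV1). NME1, a nucleoside diphosphate kinase, had 15 in set B, 14 of them in 1 library, and POLR1H, a subunit of RNA polymerase I, 15 in 1, against 0 in set A, each at least 46.6-fold higher. RPL37A had 73 reads in 2 libraries of set A and 0 in set B, at least 2.61-fold higher in set A, and TFF1 had 40 in 2 against 0, at least 1.43-fold higher. Without the deepest library the bounds were 16.3-fold for RPL13AP5 and 7.91-fold for NME1 and POLR1H. Without the library with most of their reads, NME1 and POLR1H had 1 and 0 reads in set B, and no bound. Without the deepest library the bounds were 4.64-fold for RPL37A (22 reads) and 1.05-fold for TFF1 (5 reads). The count of 5 was taken as free of error, so 1.05-fold does not establish a difference for TFF1. RPL31 had 2 of 7171 gene reads in set A and 19 of 770 in set B (ratio 0.0113, interval 0.00128 to 0.0469), LAP3, an aminopeptidase, had 1 and 10 (ratio 0.0107, interval 0.000247 to 0.0755), and RPS17 had 37 and 25 (ratio 0.159, interval 0.0931 to 0.275). The set B reads of each of these 3 genes were in 1 library (replicate 3 of NV1, 4 of NV17 and 4 of NV1), without which set B had 0 reads and the direction turned. TFF3 had 102 and 2 (ratio 5.48, interval 1.48 to 45.8), and without the deepest library 0 and 2. The ratios of RPL31, LAP3 and RPS17 were then 0.0665, 0.0632 and 0.101.

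Ribosomal protein genes took 3.12% ± 3.60 of gene reads per library in set A and 7.56% ± 10.6 in set B (n = 8 each, exact permutation p = 0.271), with a read in 5 of 8 libraries of each. Camera put the list higher in set A, opposite to these shares, and did not call it (adjusted p = 0.0832). Luminal genes took 0.635% ± 0.854 and 0.117% ± 0.332 (exact permutation p = 0.194), in 4 of 8 and 1 of 8 libraries. EdgeR called 0 of 1319 genes, with 0 at an unadjusted p under 0.05, DESeq2 0 and limma-voom 1240, of which 1239 were lower in set A (median -1.36, against 0.54 in edgeR). Its fitted log2 fold changes were 5.39 (SE 2.93) for RPL37A and 1.52 (SE 1.99) for RPS17, with edgeR's adjusted p = 1. The sign for RPS17 is opposite to that of the pooled ratio, and turned to -0.64 with singleton pairing, -0.45 with library size only and -0.45 without replicate 1 of NV1 set A.

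Libraries of set A held 167394 ± 214165 reads and those of set B 27746 ± 23340 (n = 8 each, exact permutation p = 0.00163, adjusted p = 0.0490). The difference was 225524 within NV1 (exact permutation p = 0.0857) and 53773 within NV17 (exact permutation p = 0.0286). The adjusted p rose above 0.05 when any 1 of 10 libraries was left out (replicates 2, 3 and 4 of NV17 set B, 1, 2 and 4 of NV17 set A and all 4 of NV1 set B), to at most 0.435. Genes detected were 112 ± 165 and 30.8 ± 26.3 (exact permutation p = 0.0253, adjusted p = 0.253). The adjusted p was 0.0398 without replicate 3 of NV1 set A, while without the deepest library the difference shrank from 81.5 to 24.4 genes (adjusted p = 0.300), and the highest adjusted p with 1 library left out was 0.707. Rarefied to 30 gene reads, genes detected were 20.8 ± 4.75 in set A (n = 8) and 17.3 ± 4.10 in set B (n = 5), given without a test. Set B libraries with fewer gene reads could not be rarefied. Multimapping shares were 0.380% ± 0.199 and 0.776% ± 0.616 (exact permutation p = 0.0633, adjusted p = 0.306). The difference in this share was -0.395 percentage points, and with 1 library left out it ran from -0.479 to -0.185.

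The fourth comparison set tissue against MCF-7 in NV1 libraries of set A, 4 against 2. SLC25A3 had 135 of 6264 gene reads, in 4 of 4 tissue libraries, and 0 of 488 in MCF-7, at least 3.51-fold higher in tissue, and 6 of 311 without the deepest library, at least 3.14-fold higher. Leaving out replicate 2 as well left 3 reads, which is not above the floor of 3, so no bound was set. PLIN4 had 103 reads in 2 tissue libraries and TFF3 102 in 1 against 0 in MCF-7, at least 2.67-fold and 2.65-fold higher, but 1 and 0 reads without the deepest library. MCF-7 had 31 reads of C17orf78, 17 of the cardiac homeobox gene NKX2-5 and 9 of AGAP1, a regulator of ARF GTPases, each in 1 library, against 0 in tissue. These were at least 133-fold, 72.7-fold and 38.5-fold higher in MCF-7, or 6.59-fold, 3.61-fold and 1.91-fold without the deepest library. ACTB and UQCRH had 4 reads each in 1 MCF-7 library and 0 in tissue, at least 17.1-fold higher, with no bound above 1 left without the deepest library. MAP2K7, a stress kinase upstream of JNK, had 20 reads in 1 tissue library and 28 in 1 MCF-7 library (ratio 0.0556, interval 0.0297 to 0.102), and 0 in tissue without the deepest library, at least 5.95-fold higher in MCF-7. The MCF-7 reads of each of these 6 genes were in 1 of the 2 libraries, and the other had 0.

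Of the luminal markers ESR1 had 2 reads in MCF-7 and 0 in tissue (ratio of tissue over MCF-7 0, interval 0 to 0.415, or 0 to 8.35 without the deepest library), while GATA3 and TFF1 had 8 and 35 in tissue, 7 and 35 of them in the deepest library, and 0 in MCF-7, which sets no bound above 1. BCAS1 of the list amplified in MCF-7 had 32 reads in the deepest library and 0 in MCF-7, also without a bound above 1. Ribosomal protein genes took 2.60% ± 1.87 of gene reads in tissue (n = 4) and 0.135% ± 0.191 in MCF-7 (n = 2; exact permutation p = 0.333), with RPS29, RPS17 and RPS19 at 46, 34 and 28 reads, of which 45, 33 and 27 were in the deepest library. Camera called the list higher in tissue (adjusted p = 0.0122), with an adjusted p = 0.958 with an estimated correlation. With 15 possible arrangements no exact permutation p can fall below 0.0667. EdgeR called 0 of 1319 genes, with 0 at an unadjusted p under 0.05, DESeq2 0 and limma-voom 1301, all higher in tissue (median 3.56, against 0 in edgeR). With singleton pairing and with library size only, edgeR had 220 genes each at an unadjusted p under 0.05, and still called 0. The fitted log2 fold changes were 7.45 (SE 4.89) for SLC25A3, 6.19 (SE 4.38) for TFF3 and -2.16 (SE 3.69) for MAP2K7, with edgeR's adjusted p = 0.496, 0.496 and 0.854. Without replicate 1 of MCF-7 the last became 4.05. Assigned shares were 0.290% ± 0.407 and 0.228% ± 0.0669, and genes detected were 174 ± 229 and 142 ± 139 (exact permutation p = 1 and 0.867).

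The fifth comparison set nanopipette samples against control tissue by direct RT, 6 against 2. The control libraries held 3 gene reads in all, 1 each of BRCA2, RPS11 and SLC25A36, a mitochondrial nucleotide carrier. The nanopipette libraries held 300 gene reads, led by C17orf78 (26), RGPD8 (17), the pseudogene SUZ12P1 (11), MAP2K7 (11) and HSPA8 (10), each in 1 library. BRCA2 had 1 read in each group (pooled ratio 0.01, interval 0.000127 to 0.785), and RPS11 and SLC25A36 had 0 in nanopipette samples (ratio 0, interval 0 to 0.390). Ribosomal protein reads were 2 of 300, of RPL18A and RPL27, against RPS11 alone in the controls. EdgeR called 0 of 1319 genes, with 3 at an unadjusted p under 0.05, DESeq2 0 and limma-voom 1319, all lower in nanopipette samples (median -8.28, against 0 in edgeR). The fitted log2 fold changes of -10.98 (SE 4.79) for BRCA2 and -12.09 (SE 4.14) for RPS11, with edgeR's adjusted p = 1, rest on 1 control read each. Without replicate 2 of the controls that of BRCA2 became 1.96. Multimapping shares were 0.585% ± 0.145 (n = 6) and 1.27% ± 0.592 (n = 2; exact permutation p = 0.0357, the smallest that 28 arrangements allow, adjusted p = 0.262). The control shares rest on 12 and 3 multimapping reads, in libraries of 710 and 352 reads. The difference was -0.686 percentage points, and with 1 library left out it ran from -1.10 to -0.267. Assigned shares were 0.189% ± 0.0942 and 0.283% ± 0.00170 (exact permutation p = 0.357). The control shares rest on 2 of 710 and 1 of 352 reads. Their exact binomial intervals were 0.0341% to 1.01% and 0.00719% to 1.57%, so the small SD does not mean a precise share.

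The 4 NV13 control libraries have no replicates, so their differences have no replicate check. In MCF-7, the library with the 3day label held 272 gene reads and the other 175, with 0 genes in both among those with a symbol and a position. The 3day library had 83 reads of NAV2, which guides cell migration, 46 of PFKFB3 and 31 of the zinc finger gene ZNF16, against 0 in the other. These were at least 17.8-fold, 9.87-fold and 6.65-fold higher, with log2 ratios of 6.75, 5.90 and 5.34. The other library had 40 reads of RGPD8 (log2 ratio -6.98, at least 20.7-fold higher), 13 of HSPA8, 9 of ribosomal protein genes and 3 of MALAT1, against 0, 0, 1 and 0. The 2 tissue libraries held 139 and 158 gene reads, with 2 genes in both among those with a symbol and a position. In tissue, the library without the 3day label had 36 reads of the quinone reductase NQO2 (log2 ratio -6.00, at least 10.6-fold higher) and 22 assigned to the nuclear pseudogene MTCO2P12 (log2 ratio -5.31, at least 6.45-fold higher), against 0. Mitochondrial-chromosome genes were not among the rows used, so a mitochondrial origin of the MTCO2P12 reads could not be checked. The 3day tissue library had 3 reads of the luminal genes KRT19 and ERBB2 and 2 of RPL23A and RPSA, against 0. The assigned share was 0.318% (interval 0.281 to 0.358) in MCF-7 3day and 0.205% (0.175 to 0.237) in the other MCF-7 library. It was 0.214% (0.180 to 0.252) in tissue 3day and 0.0698% (0.0594 to 0.0816) in the other tissue library.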

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

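Total reads and exon share were added as measures after the results were seen. Genes detected had been planned after rarefaction to 10000 gene reads, a depth that 0 libraries reached. The number without rarefaction, which rises with depth, was used in its place. The other measures were fixed in advance. In groups of 4 or more libraries, a library was picked out when its gap to the nearest other library was large against the range of its group. Of 30 values tested this way 10 were picked out. A chance rate of about 1 in 20 holds for independent normal values. Here the shares are parts of the same total and several picks came from the same library, so the 10 cannot be set against that rate.

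Replicate 4 of tissue NV17 set A had a multimapping share of 0.630%, where the other 3 libraries had 0.311% to 0.349%. Its assigned share was 0.636%, where the others had 0.223% to 0.286%. Replicate 2 of tissue NV17 set B, with 723 reads in all, had an unmapped share of 64.3%, where the others had 93.8% to 98.0%. The multimapping share of the same library was 2.21%, against 0.447% to 0.688%, and its assigned share was 3.04%, against 0.0559% to 0.527%. Replicate 3 of tissue NV17 set B had 1 gene with a read, where the others had 19 to 22.

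Replicate 1 of tissue NV1 set A, the deepest library, had an unmapped share of 88.2%, where the others had 97.6% to 99.2%. Its multimapping share was 0.744%, against 0.198% to 0.270%, its assigned share 0.899%, against 0.0527% to 0.126%, and its genes with a read 517, against 35 to 80.

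The share of uniquely aligned reads on exons was picked out because the difference between NV1 and NV17 was not the same in the 2 sets. It was -2.11 percentage points in set A and 4.42 in set B, a difference of -6.53 (permutation p = 0.0143, not adjusted). This was the smallest p of 6 measures tested this way, where the others ranged from 0.396 to 0.816. The difference between NV1 and NV17 had an exact permutation p = 0.171 in set A and 0.114 in set B.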

How the results depend on the processing

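Libraries left out for low depth, exon share, total reads and list shares were chosen after the results were seen, and the other alternatives were planned. Of 987 alternative values 889 were classed as unchanged, in direction and side of the threshold where these apply. Most reported values lay far from the threshold, so this number says little about robustness. With a median of 95 gene reads per library, depth limits every gene-level result, since a stricter filter left 0 genes and rarefaction to 1000 reads left 1 library.

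The number of genes called stayed at 0 under every left-out library, DESeq2's size factors and Wald test, the groups compared alone and the larger strand column. Limma-voom called 1310, 1318, 1240, 1301 and 1319 genes in the 5 comparisons in the order of the report. Within each comparison these calls went in 1 direction, apart from 1 gene in set A against set B. Signs that turned in limma-voom therefore cannot be told from a shift of nearly all genes. TMM with singleton pairing and library size only each called 1 gene in NV against direct RT. In limma-voom the log2 fold change of C17orf78 turned to 2.43, RGPD8 to 2.58 and HSPA8 to 2.44 in NV against direct RT. It turned to -1.14 for RPS17, -1.77 for TFF3 and -2.08 for HSPA8 in NV1 against NV17, to -0.96 for RPS17 and -0.51 for RPL37A in set A against set B, and to 0.27 for MAP2K7 in tissue against MCF-7. RPS17 in set A against set B turned to -0.64 with singleton pairing and -0.45 with library size only. The cause was not tested.

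With 1 library left out, log2 fold changes ran from -12.93 to 1.96 for BRCA2 in direct RT, -3.98 to 1.82 for HSPA8 and -5.86 to 2.06 for RGPD8 in NV against direct RT, -6.46 to 4.05 for MAP2K7 in tissue against MCF-7 and -0.45 to 4.02 for RPS17 in set A against set B. The ribosomal protein share difference ran from 3.33 to 7.55 percentage points in NV1 against NV17 and from -49.6 to 0.412 in direct RT.

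Camera's calls of the ribosomal protein list were lost with an estimated correlation (adjusted p = 0.958 in NV1 against NV17, NV against direct RT and tissue against MCF-7). Fry turned the direction of that list in the first 3 comparisons (adjusted p = 0.520, 0.953 and 0.520) and did not call it in tissue against MCF-7 (adjusted p = 0.520). It also turned the luminal list in the same 3 comparisons (adjusted p = 0.520, 0.953 and 0.520) and in direct RT (adjusted p = 0.118), and the housekeeping list in set A against set B (adjusted p = 0.520) and direct RT (adjusted p = 0.118). The cause was not tested.

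Among the differences per library, in percentage points for shares, NV1 less NV17 turned to 0.225 for the assigned share and 2.65 for the multimapping share over aligned reads alone. Without libraries under 10000 reads it turned to 0.131 for assigned, 0.0422 for multimapping and -1.29 for unmapped. In set A less set B the same step gave 0.0909 for assigned, 0.189 for exon share and -1.04 for unmapped. Medians gave -0.123 for assigned and -70 genes detected in tissue less MCF-7, 1.29 for unmapped in NV less direct RT and -0.208 for unmapped in direct RT. Total reads of set A less set B were 103849 as medians and 130381 without libraries under 10000 reads, and lost their call. The cause was not tested.

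With 1 library left out, NV1 less NV17 ran from -0.441 to 0.0566 for assigned, -0.287 to 0.00755 for multimapping, -0.594 to 5.03 for unmapped, 19.9 to 100.2 for genes detected and 57728 to 160428 for total reads. Set A less set B ran from -0.481 to 0.0165 for assigned, -0.338 to 5.28 for unmapped, 24.4 to 105 for genes detected and 74592 to 177293 for total reads. Tissue less MCF-7 ran from -0.140 to 0.142 for assigned, -1.33 to 2.72 for exon share, -1.46 to 3.15 for unmapped and -82.5 to 130 for genes detected. NV less direct RT ran from -0.116 to 0.0342 for multimapping, and nanopipette less control from -2.10 to 2.25 for unmapped. The median correlation between libraries moved to 0.579 within groups and -0.167 between groups when only genes with 100 counts or more were kept, which left 7 genes, 6 pairs within groups (-0.0477 to 1) and 30 pairs between groups.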

Other observations

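All tests in this part were chosen after the results were seen. The real grouping called 0 genes in NV1 against NV17, NV against direct RT and set A against set B, so all 100 splits of the libraries call as many in each by construction, and they say nothing about chance. The highest count in another split was 0, 193 and 0. In NV against direct RT 6 of the 100 splits called any gene, and the cause was not tested.

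Of the uniquely aligned reads, 8.36% fell on exons, while exons cover 4.35% of the genome span and whole genes 53.1%. A read has a length and can touch an exon from outside it. Exons widened by 50 and 100 bases on each side cover 5.35% and 6.27%. Placement without regard to genes was tested with the ribosomal protein list, of which 27 members had a read where length-matched lists had a mean of 3.85, so some reads are likely from transcripts. Spliced messenger RNA of the genes with a row would alone put most reads on exons, which the 8.36% rules out as the only source. Reads from DNA or unspliced RNA could fill the rest. So could reads of the mitochondrial chromosome, whose genes were not among the rows used, so that its reads could count as outside exons. The files cannot separate these sources. Tissue against MCF-7 as the source could not be told apart (exact permutation p = 0.667).

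C17orf78, SUZ12P1 and CPAMD8 were each seen in exactly 2 libraries, of different groups, with 26 and 31, 11 and 15, and 7 and 11 reads, while TFF3 had 2 and 102 and ADCY6 4 and 38. Of 94 such genes 28 were in libraries whose library numbers, given in the labels' descriptions and not the replicate numbers used here, end in the same digit, against a mean of 9.06 with permuted numbers (permutation p = 0.0012), and 14 of 47 against 4.54 without the deepest library (permutation p = 0.0035), so carry-over between libraries with the same last digit may explain part of the sharing. Adjacent library numbers showed no such excess, with 2 of the 94 genes against a mean of 5.67 (permutation p = 0.874). Counts were within 2-fold for 17 of the 28 genes, and for 6 of the 11 with 2 or more reads in both libraries. Libraries of the same group also shared more genes, 22 of 69 without the deepest library against a mean of 6.52 (permutation p = 0.0012), while the same source, tissue or MCF-7, gave 128 of 165 against a mean of 126 (permutation p = 0.662), which leaves a shared tissue open. C17orf78, the single gene called under some scalings, is among the 28, so its fold may not be biological. TFF3, RPL32 and HSP90AB1 are also among the 28, each shared with the deepest library. Leaving out that library in the list results may therefore not remove all reads carried over from it.

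BRCA1 and BRCA2 had reads in 10 of 30 libraries each, with 12 and 11 reads. Exon length predicts 0.564 and 0.726 libraries (exact p over the libraries' gene reads = 1.22e-13 and 1.97e-12), so long exons do not explain them, and a highest count of 2 reads in any library speaks against carry-over from 1 rich library. Of 20 other hereditary cancer panel genes 7 had a read, against a mean of 1.56 in length-matched lists (permutation p = 0.0004; 0.0002 without the deepest library). Those lists were not matched on expression, and the ribosomal protein, luminal and housekeeping lists also passed this test (permutation p = 0.0001, 0.0001 and 0.0002). The test therefore cannot tell DNA of a panel from transcripts of these genes. Against DNA of a panel as the only source, the pseudogene KARS1P3 was also in 10 libraries, where 0.102 were expected, and MARCHF6 in 7. The source of these reads remains open.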
